A study of Mus musculus with 4 samples.

How the data were processed

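RNA levels were measured with Illumina bead arrays in neural stem and progenitor cells (NSPC) taken from mouse neocortex and grown as neurospheres. Per the labels' protocols, the cells stood in suspension in serum-free medium with EGF and FGF2 at 20 ng/ml each, the spheres were harvested at day 5, RNA was extracted with Trizol and treated with DNase, and biotinylated cRNA was hybridised. The labels name 2 groups of 2 biological replicates each, cells of a transgenic line that overexpressed Bmi1 and transgenic control cells, all on the C57BL/6 background.

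The authors deposited a scanner table and a processed table of the same 4 arrays. Per the file headers, the scanner table gives a signal intensity and a detection p-value for each probe and array. The deposited intensity values had already been background-subtracted, since 31.2 to 33.9% of the signals of an array lay at or below 0. The deposited detection column rose with the signal (rank correlation across probes 0.980 to 0.987), so it was read as 1 minus the p-value. Of the rows of that table, 22 carried no probe identifier and were left out, which left 45259 probes. The deposited processed table holds log2-like values with a common minimum of 4.71 and maximum of 15.13 and column medians of 5.69, as quantile normalization gives. It is compressed at low signal, and its exact transform, its background step and the settings behind it are not given in the sources used here. Per the submitters' processing notes, lumi was used, with no version stated.

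The 2 tables name the groups in opposite ways. Each column of the processed table was set against each array of the scanner table by Spearman correlation across probes, and by the correlation of deviations from the mean of the 4 arrays over probes with a signal above 200 on each array. Each column had 1 clear partner, and the columns of the control samples matched the arrays headed as Bmi1 cells in the scanner table, while the columns of the Bmi1 samples matched the arrays headed as controls. Groups were named by the scanner headers. The sample descriptions in the labels give 5CTR and 7CTR for the controls and 1DT and 2DT for the Bmi1 cells, while the headers read 5CTR, 7CTR and, for both remaining arrays, 1DT. Whether 1 of these is the array described as 2DT is not given in the sources used here, so they are called the first and the second Bmi1 array by their place in the table. The direction of every difference is therefore not settled, and the processed values with groups as their own columns name them were run as an alternative.

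Signals were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which fits a normexp background from the detection p-values where no control probes are given, adds an offset of 16, takes log2 and equalises the quantiles of the arrays. A probe was kept when its detection p was under 0.05 on at least 2 of the 4 arrays, whatever their group, which left 18237 probes. The annotation given with the array pairs 34872 probes with 1 gene symbol, 18 with several and 10369 with none, and 34794 probes have a gene identifier in the current reference table, through which older symbols were updated. Each gene was represented by its probe with the highest mean log2 value over the 4 arrays, and a probe without a single gene name stayed a feature of its own. This gave 12809 features, 10044 of them named genes. Where another detected probe of a named gene had the opposite sign, its value is given. A gene below detection on both arrays of a group is described by its signals.

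The groups were compared with lmFit and eBayes of limma, with group as the only term, a two-sided test and Benjamini-Hochberg adjustment over the 12809 features at a threshold of 0.05. Log2 differences are those of the arrays labelled Bmi1 minus the arrays labelled control, with the standard error (SE) of the moderated fit, and its total degrees of freedom were 7.23. Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 41 lists with at least 3 measured members, and again with an estimated correlation and with fry. The 43 lists covered polycomb complexes and developmental regulators, cell cycle and DNA repair, apoptosis and p53 targets, progenitor, neuronal and glial markers, other cell types the cultures could hold, signalling, metabolism and stress. Of their 1077 entries, 1070 matched a current symbol. Members were also adjusted over their list alone. In these data 22.0% of all features had an unadjusted p under 0.05. Single members can therefore pass over a list alone without a difference particular to that list. With 2 arrays per group, the number of arrays limits the precision of every value. The scanner table gives no slide or scan date, so no batch was tested.

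The model, the filter, the lists, the named genes and the alternatives were chosen before the data were examined. The genes named are Bmi1, the 10 genes in each direction with the largest change among those that passed (places left going to the smallest unadjusted p with both arrays labelled Bmi1 on the same side of both controls), 10 genes of interest for this protein and these cells, 4 members of smallest p for each list that passed, and at most 2 for any other list. Of the genes of interest, 1 is not reported here. Genes named outside this rule are said to have been chosen after their values were seen. The alternatives were the processed table, no background correction (signals below 1 set to 1), an offset of 50, cyclic loess or median scaling in place of quantiles, no filter, a detection p under 0.01 on all arrays, all probes or the mean of a gene's probes, eBayes with trend and robust (for the lists, camera with a variance trend), the replicate number as a block (the scanner headers carry none, so each array took that of its matched column in the processed table), each array left out in turn, an adjusted p under 0.1, and a fold of at least 1.5. Where an array was left out, the single array left in its group was assumed to vary like the other group.

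The fits were tested on simulated data made from the measured means and the fitted spread of the 12809 features, with 200 features changed in each of 10 runs. Of 500 features changed by a log2 difference of 1, 80 were recovered, and of 500 each at 2, 3 and 4, 472, 497 and 500 were recovered. The calls held 103 features that had not been changed, 6.23% of the calls. These recovery rates hold for the simulated spread only. In the data, log2 differences of -3.84 (SE 0.77) for Mbp, -3.14 (SE 0.48) for Ap2a1 and -2.74 (SE 0.63) for Gfap did not pass. In 50 runs with no change, camera called a list in 1 run, and it called a mitotic list shifted as in the data in 50 of 50 runs. When the genes of that list were given a shared array-to-array spread with an SD of 0.5 and no group effect, it was called in 26 of 50 runs, so the preset correlation does not guard against genes that vary together from culture to culture.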

Results

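Gene expression was profiled in neurosphere cultures of neural stem and progenitor cells (NSPC), cells that self-renew and give rise to neurons and glia, from the mouse neocortex. The design compared cells overexpressing Bmi1, a subunit of polycomb repressive complex 1 that silences the Ink4a-Arf locus and sustains self-renewal, with transgenic control cells, and asked which transcripts differ between them. Each group held 2 biological replicates with 1 array each. Of 45259 probes, 18242 were detected on control array 1, 18208 on control array 2, 17742 on the first Bmi1 array and 16495 on the second Bmi1 array. The mean signal was 228, 233, 215 and 191 in that order, so the second Bmi1 array was the dimmest.

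The 2 deposited tables of these arrays name the groups in opposite ways. The columns of the processed table filed under the control samples correlated at 1.00 (Spearman, across probes) with the 2 arrays headed as Bmi1 cells in the scanner table, and at most at 0.898 with any other array. The columns filed under the Bmi1 samples correlated at 1.00 with the 2 arrays headed as controls, and at most at 0.899 with any other. Both tables split the 4 arrays into the same pairs, so sizes and p-values stand, but the sign of every difference depends on which table is right. Below, arrays are named by the scanner headers as arrays labelled Bmi1 or labelled control, and each direction turns if the processed table is right.

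**Figure D1:**
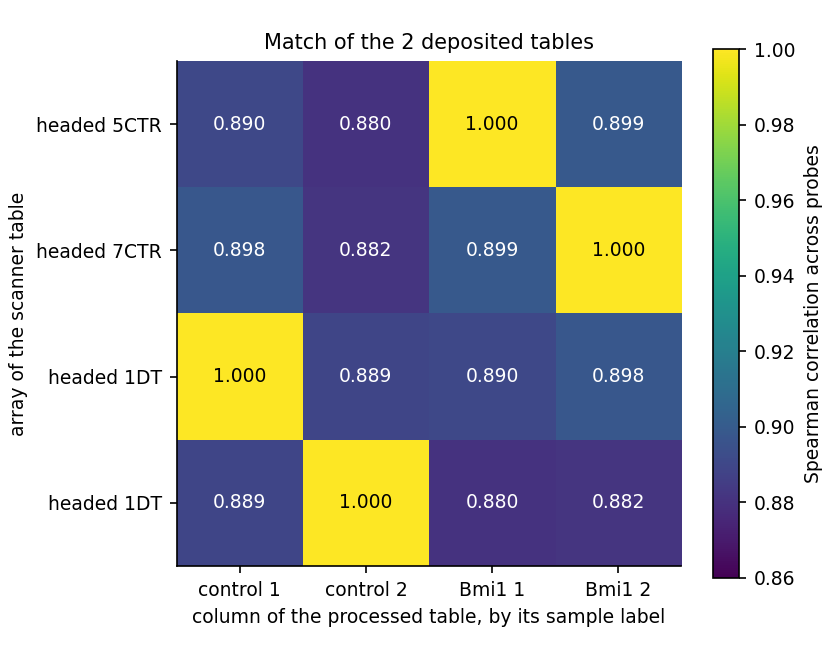
Spearman correlation across probes between each array of the scanner table (vertical axis, by its header) and each column of the processed table (horizontal axis, by its sample label). Each column has 1 partner at 1.00, and the columns of the control samples pair with the arrays headed 1DT.

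Bmi1 itself did not settle the names. It was measured by 1 probe, with background-subtracted signals of 79.4 and 62.7 on the control arrays and 53.3 and 77.7 on the arrays labelled Bmi1, all detected. The log2 difference was 0.24 (SE 0.29, adjusted p = 0.667), smaller than the spread between replicates, and the arrays of the groups overlapped. Leaving out the second Bmi1 array turned it to -0.13, and leaving out the first raised it to 0.61. Where the probe lies relative to the transgene's transcript is not given in the sources used here, so this probe does not check the labels.

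**Figure D2:**
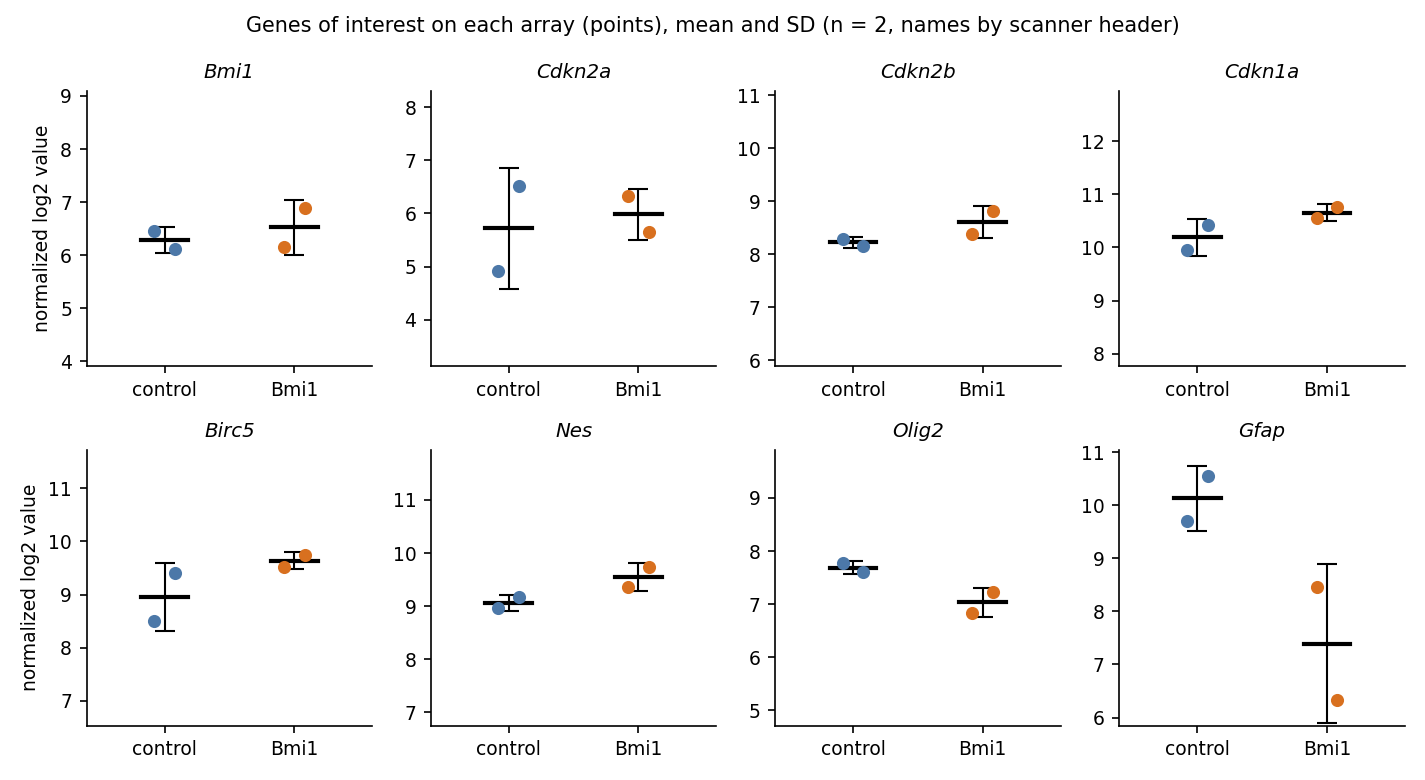
Normalized log2 values (vertical axes, each spanning the same range) of Bmi1 and 7 other genes of interest on the 2 arrays of each group, with bars for the mean and whiskers for the SD (n = 2), and group names by scanner header. Gfap shows the widest gap between groups, from 10.13 to 7.39, and Bmi1 and Cdkn2a overlap between groups.

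In the comparison of the groups, genes of cell division were higher and genes of astrocytes and oligodendrocytes lower in the arrays labelled Bmi1, with the reverse under the processed table's names. As groups these genes passed with camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.982 for each list) or with fry (adjusted p of 0.439 to 0.613). Among single genes, none of which passed, Plk1, a kinase that drives entry into mitosis, was at 10.59 ± 0.71 on the log2 scale in the arrays labelled Bmi1 against 8.65 ± 0.56 in the controls (mean ± SD, n = 2 each). Myelin basic protein (Mbp) was at 6.32 ± 0.94 against 10.16 ± 1.79, and the astrocyte filament protein Gfap at 7.39 ± 1.5 against 10.13 ± 0.61, a difference of -2.74 that was -1.67 without the second Bmi1 array. None of the 12809 features passed with limma at an adjusted p of 0.05, and the smallest adjusted p was 0.133, shared by 465 features. At an unadjusted p under 0.05 there were 2817 features, where chance gives 640, of which 1567 (55.6%) were higher and 1250 lower in the arrays labelled Bmi1. With median scaling, which shifted the median difference of all features to 0.13, the split was 2162 (68.7%) higher and 984 lower. Both arrays of 1 group lay on the same side of both arrays of the other for 7024 features (54.8%), where chance gives 33.3%. All features come from the same few arrays and vary together. The chance values of 640 and 33.3% are therefore averages, and counts far from them can arise without a group effect. The 2817 features became 1067 without control array 1 and 1428 without the second Bmi1 array. Without control array 2, 5 features passed, and without the first Bmi1 array 1 did (the metallothionein Mt3, chosen after its value was seen, at -4.19 with an adjusted p of 0.0461).

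The genes with the smallest unadjusted p were of mixed kinds, and none passed the adjusted test (adjusted p = 0.133 for each). On the side higher in the arrays labelled Bmi1, the log2 differences were 1.58 for Fryl, 1.65 for Retsat, a retinol saturase, 1.37 for Nsmf, 1.33 for the mitochondrial respiratory chain gene ND5, 1.46 for Abtb1, 1.46 for Mast2, a kinase, 1.28 for Rpap3, 1.25 for Atp13a1, 1.22 for Slc27a3, and 1.19 for Mvb12a. The SE of these 10 ranged from 0.19 for Nsmf to 0.23 for Mast2. The ND5 probe lay near the floor on the control arrays, at log2 values of 4.86 and 4.94. It was at 6.35 and 6.11 on the arrays labelled Bmi1. Lower were Ap2a1, a subunit of the endocytic adaptor complex, by -3.14 (SE 0.48), Rnd2 by -2.05 (SE 0.32), and the selenoprotein Selenow by -2.03 (SE 0.34). Also lower were Tomm6 (-1.88) of the mitochondrial import pore, Rbck1 (-1.65), Mospd3 (-1.60), Pym1 (-1.57), Lbh (-1.37), Ube2v1 (-1.34), and Atp1b2 (-1.28), a sodium pump subunit of glia. Of the 10 higher genes, 6 had another detected probe, and 3 of those had a probe of opposite sign, at -1.02 and -0.24 for Nsmf, -0.80 for Retsat and -0.78 for Atp13a1. Of the 10 lower genes, 4 had another detected probe, and 0 had one of opposite sign.

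Genes of mitosis and of DNA replication were higher as groups in the arrays labelled Bmi1. Of 23 mitotic genes measured, 22 were higher, with a median log2 difference of 0.98 (camera adjusted p = 2.46e-07, adjusted p = 0.982 with an estimated correlation). With p adjusted over the list alone 13 passed, all higher, and over all features 0 passed. They included Plk1 at 1.94 (SE 0.39), Dlgap5, a spindle assembly protein, at 1.32 (SE 0.29), Kif11, the motor that separates spindle poles, at 1.19 (SE 0.29), and Ndc80 of the kinetochore at 1.12 (SE 0.28). Of 34 genes of DNA replication and the G1-S transition, 31 were higher, with a median of 0.66 (adjusted p = 2.46e-07, adjusted p = 0.982 with an estimated correlation). Adjusted over the list alone 7 passed, among them the polymerase subunit Pold1 at 1.44 (SE 0.35), the replication licensing factor Cdt1 at 1.67 (SE 0.43), Gins1 at 1.15 (SE 0.30), and Uhrf1, which maintains DNA methylation after replication, at 1.58 (SE 0.42). Of 21 DNA repair genes, 16 were higher, with a median of 0.48 (adjusted p = 0.0480, adjusted p = 0.982 with an estimated correlation). Adjusted over the list alone none of them passed with limma, and the members of smallest p were Fancd2 at 1.02, Mre11a at 1.09, Msh6 at 0.93, and Brca2 at 0.64.

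The arrays within a group also differed in these lists, by medians of 0.82 between the controls and 0.48 between the arrays labelled Bmi1 for the mitotic list, 0.68 and 0.57 for replication, and 0.29 and 0.31 for DNA repair. Relative to each gene's mean over the 4 arrays, the mitotic median was -0.86 on control array 1, -0.07 on control array 2, 0.23 on the first Bmi1 array and 0.73 on the second. The replication median was -0.70, 0.00, 0.08 and 0.61 in the same order. Without control array 1 the mitotic median fell by over 1.5 times to 0.49 and the replication median to 0.36, with both lists still past the threshold. Without control array 2 the replication median was 1.09, and with no filter on dim probes the mitotic median was 0.61. The DNA repair list passed in 6 of 16 alternatives run with camera at its preset correlation. Its median was 0.18 without control array 1 and 0.19 without the second Bmi1 array, where it did not pass. Among the single genes, Cdt1 was 1.06 without control array 1, and Mre11a was 0.69 and Msh6 0.55 without the second Bmi1 array.

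Glial markers were lower as groups in the arrays labelled Bmi1. Of 23 astrocyte markers, 19 were lower, with a median log2 difference of -0.32 (camera adjusted p = 0.00121, adjusted p = 0.982 with an estimated correlation). Adjusted over the list alone 8 passed, all lower, and over all features 0. They included Gfap at -2.74 (SE 0.63, and -1.67 without the second Bmi1 array), with a dimmer probe at -1.0, Atp1b2 at -1.28 (SE 0.20), the water channel Aqp4 at -1.21 (SE 0.27), and the peptide-processing enzyme Cpe at -0.90 (SE 0.21). The astrocyte list passed in 16 of 16 alternatives run with camera at its preset correlation, but not with an estimated correlation or fry. Its median was -0.67 with a detection p under 0.01 on all arrays and -0.61 with no background correction. Relative to each gene's mean, its median was 0.27 and 0.17 on control arrays 1 and 2. It was -0.17 on the first and -0.19 on the second Bmi1 array. Of 19 oligodendrocyte lineage markers, 15 were lower, with a median of -0.75 (adjusted p = 0.00205, adjusted p = 0.982 with an estimated correlation). Adjusted over the list alone 3 passed, Mbp at -3.84 (SE 0.77), the lineage transcription factor Nkx2-2 at -1.16 (SE 0.22), and the myelin glycoprotein Mag at -2.06 (SE 0.56). Bcas1, a marker of early myelinating cells, stood at -1.69 (SE 0.52), and the lineage factor Olig2 at -0.65 (SE 0.22), and neither passed. The other Mbp probes stood at -0.25 and -1.23. Without control array 1, Mag was at -1.07 and Bcas1 at -0.92.

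The oligodendrocyte difference lay mostly in 2 of the arrays. The list's median relative to the mean of the 4 arrays was 1.01 on control array 1, 0.00 on control array 2, -0.07 on the first Bmi1 array and -0.67 on the second. It was -0.22 without control array 1, -0.47 without the second Bmi1 array and -1.35 without control array 2, and it did not pass without either of the first 2 of these, nor with no filter on dim probes (adjusted p = 0.0814). Control array 1 was also the array with signal for Xist, the transcript of the inactive X chromosome, at 115 to 971 over 4 probes against at most 8.4 on any other array. The Y-linked gene Eif2s3y gave -1.8 there and 205 to 240 on the other 3 arrays by its brighter probe.

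**Figure D3:**
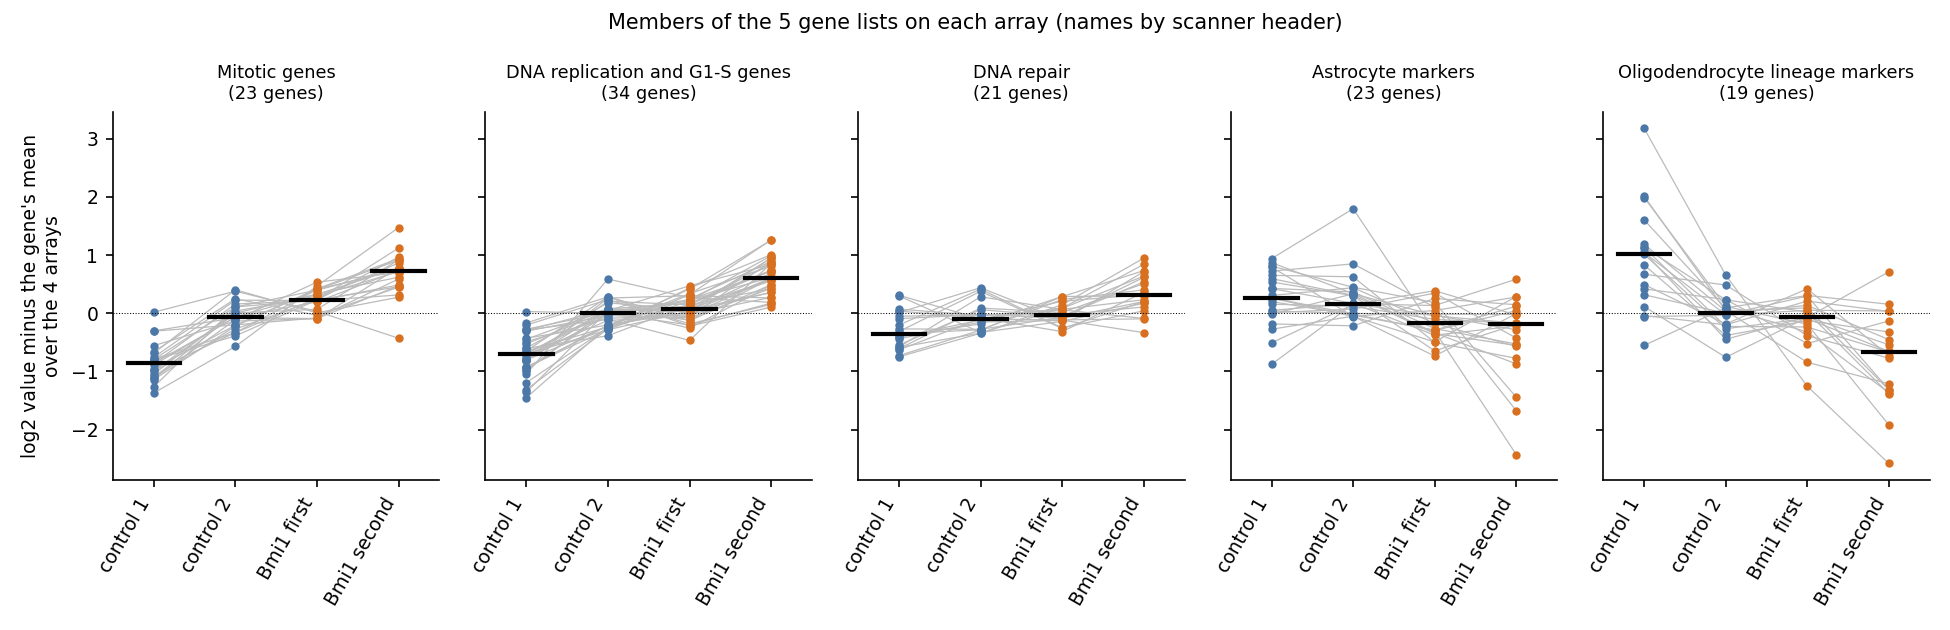
Log2 value of each member of the 5 lists that passed, minus that gene's mean over the 4 arrays (vertical axis), on each array (horizontal axis, named by scanner header), with points for genes, grey lines joining the values of 1 gene and black bars for the list median. Control array 1 and the second Bmi1 array lie farthest apart, at mitotic medians of -0.86 and 0.73 and oligodendrocyte medians of 1.01 and -0.67.

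None of the lists of known targets and partners of Bmi1 passed. The Ink4a-Arf gene Cdkn2a stood at 0.27 (SE 0.50, adjusted p = 0.794), with its other probes at 0.39 and 0.49, and its sign turned to -0.54 without control array 1 and -0.07 without the first Bmi1 array, and it was 1.07 without control array 2. Cdkn2b was at 0.38 (SE 0.22, adjusted p = 0.362) and Cdkn1a, the p21 inhibitor, at 0.47 (SE 0.24, adjusted p = 0.293). Cdkn2b was 0.59 without the first and 0.17 without the second Bmi1 array, and Cdkn1a 0.23 without control array 1 and 0.71 without control array 2. The 7 measured cyclin-dependent kinase inhibitors had a median of 0.27 (adjusted p = 0.469) and did not pass. The 20 measured subunits of polycomb repressive complex 1 had a median of -0.12 (adjusted p = 0.995), with Scmh1 at -0.85 and Phc2 at 0.72. The 9 subunits of complex 2 had a median of 0.25 (adjusted p = 0.236), and adjusted over the list alone Eed at 0.92 (SE 0.21) and Mtf2 at 0.93 (SE 0.24) passed. The complex 2 list passed with all detected probes tested separately (adjusted p = 0.0220) and without control array 2 (adjusted p = 0.0421), against an adjusted p = 0.982 with an estimated correlation on all arrays. The 5 measured Hox genes, classical polycomb targets, had a median of 0.28 (adjusted p = 0.443). Hoxa13 stood at 0.52 (its other probe at -0.19) and Hoxa4 at 0.40 (0.22 without the second Bmi1 array). All 5 lay near the floor, with log2 values from 4.32 to 5.52 over the arrays. The 19 other homeobox regulators had a median of -0.07 (adjusted p = 0.963), and adjusted over the list alone Nkx2-2 at -1.16 and Gbx2 at 0.91 (SE 0.22) passed.

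Markers of progenitors and neurons did not pass as groups. The 19 neural stem cell and radial glia markers had a median of -0.01 (adjusted p = 0.772). Among them the receptor Notch1 at 1.00 (SE 0.21) passed when adjusted over the list alone, while the matrix protein Tnc at 0.69 (1 of its other probes at -0.16) and the filament protein nestin (Nes) at 0.49 (SE 0.22, adjusted p = 0.246) did not, and without the second Bmi1 array these 2 were 0.39 and 0.31. Neuronal markers, 22 of them, had a median of -0.13 (adjusted p = 0.443). Adjusted over the list alone Thy1 at -1.25 (SE 0.29) and the RNA-binding protein Elavl3 at -1.31 (SE 0.30) passed as lower, and 1 gene passed as higher, Bcl11b at 0.92, chosen after its value was seen, with its other probe at -0.23. The intermediate progenitor list had 4 measured members and a median of 0.00 (adjusted p = 0.963), and the GABAergic list had 3 and a median of 0.09 (adjusted p = 0.963). Markers of the dorsal telencephalon had a median of 0.11 (adjusted p = 0.801) and ventral and caudal markers 0.07 (adjusted p = 0.772). The 2 probes of Eomes and the 1 probe of Tubb3 were each detected on fewer than 2 of the 4 arrays, so these genes were not tested.

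None of the lists of cell death and stress genes passed. Birc5, the apoptosis inhibitor survivin, which also acts in mitosis, stood at 0.68 (SE 0.31, adjusted p = 0.250), and its other probes at 1.00 and 1.09, while without control array 1 it was 0.23 and without control array 2 it was 1.13. The 8 apoptosis inhibitors had a median of 0.20 (adjusted p = 0.635), and adjusted over the list alone Cflar at 0.68 (SE 0.21) and Bcl2l1 at -0.96 (SE 0.30) passed in opposite directions, as did Mcl1 at 0.62, chosen after its value was seen. The 15 apoptosis effectors had a median of 0.11 (adjusted p = 0.853). Adjusted over the list alone Bbc3 at 0.89 (SE 0.22), which encodes Puma, and Apaf1 at 0.82 (SE 0.21) passed as higher. The other Bbc3 probe stood at 0.02, and the other Apaf1 probes at 0.21 and 0.92. The 17 p53 target genes had a median of 0.30 (adjusted p = 0.443), with Plk2 at 1.04. Heat shock genes had a median of 0.30 (adjusted p = 0.481), with Hsph1 at 0.97 (SE 0.20) passing when adjusted over the list alone, and immediate early genes 0.30 (adjusted p = 0.397), with Dusp1 at 1.15. The immediate early list passed without the first Bmi1 array, with a median of 0.68 (adjusted p = 0.0416), against an adjusted p = 0.982 with an estimated correlation on all arrays. Without the second Bmi1 array Plk2 was 0.64 and Dusp1 0.61, and without control array 1 Bcl2l1 was -0.56. Unfolded protein response genes stood at 0.19 (adjusted p = 0.665), redox defence genes at -0.14 (adjusted p = 0.635), interferon response genes at 0.00 (adjusted p = 0.995), and senescence secretory genes at 0.23 (adjusted p = 0.714).

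Signalling and metabolic lists did not pass either. The median log2 difference was -0.22 for the Notch pathway (adjusted p = 0.696), -0.09 for the BMP and TGF-beta pathway (adjusted p = 0.635), 0.04 for the Wnt pathway (adjusted p = 0.877), 0.01 for the Hedgehog pathway (adjusted p = 0.971), and 0.08 for feedback genes of EGF, FGF and MAPK signalling (adjusted p = 0.877). Single members stood farther out, with the Wnt effector Tcf7l1 at -1.88 (SE 0.43), Bmp4 at -2.02 (SE 0.57), Id2 at -0.75 (SE 0.20, its other probe at 0.07), and Ier3 at 1.05 (SE 0.28), none of which passed over its list alone. In the Notch list, 1 member passed over the list alone, as higher. Without the second Bmi1 array Tcf7l1 was -1.15, and without control array 1 Bmp4 was -1.09. Glycolysis and hypoxia genes had a median of -0.20 (adjusted p = 0.503), oxidative phosphorylation genes -0.11 (adjusted p = 0.665), cholesterol synthesis genes 0.05 (adjusted p = 0.635), and cytosolic ribosomal proteins -0.08 (adjusted p = 0.533). Extracellular matrix genes had a median of -0.15 (adjusted p = 0.853), and adjusted over the list alone 3 passed, among them Bcan at -1.36 (SE 0.26) and Lamc1 at 0.93 (SE 0.20), though the other Lamc1 probe stood at -0.86. Imprinted genes had a median of 0.35 (adjusted p = 0.635), and adjusted over the list alone 2 passed as higher and 2 as lower, the latter being Gnas at -1.12 (SE 0.23, with 1 of its other probes at 0.27) and Nnat at -0.87 (SE 0.20).

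None of the lists of markers of other cell types passed. Of 20 microglia and macrophage markers, 4 were measured, with a median of 0.37 (adjusted p = 0.309). Aif1 was not detected on the control arrays, with normalized log2 signals of 4.38 and 4.49 against 4.90 and 4.89 in the arrays labelled Bmi1. The bound of at least 1.25-fold rests on values near the floor. The log2 difference of 0.46 (SE 0.19) did not pass with limma (adjusted p = 0.224). Mesenchymal and meningeal markers had 5 measured members and a median of 0.27 (adjusted p = 0.963), ependymal and choroid plexus markers 6 and -0.02 (adjusted p = 0.963), and neural crest and Schwann markers 6 and -0.06 (adjusted p = 0.995). The sex-linked check genes had 4 and 0.21 (adjusted p = 0.963). With 2 of them higher, among them Eif2s3y, and 2 lower, among them Xist, this test of direction says nothing about sex. Endothelial markers had 1 measured member and erythroid markers 0, so these lists were not tested. In all, 5 of 41 lists passed with camera, 0 passed with an estimated correlation or with fry, and 0 and 2 lists had an unadjusted p under 0.05 in those tests. The median and the mean, or the median and the test, differed in sign for the cholesterol, radial glia, Wnt, other homeobox, ependymal, intermediate progenitor, Hedgehog, polycomb complex 1, neural crest and interferon lists, none of which passed with camera.

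Arrays correlated closely within and between groups. Across genes, which are not independent replicates, Pearson's r was 0.986 between the control arrays, 0.982 between the arrays labelled Bmi1, and 0.958 to 0.986 between arrays of different groups, the highest being that of control array 2 with the first Bmi1 array. The SD of the log2 differences was 0.38 between the control arrays and 0.43 between the arrays labelled Bmi1. Between means of 2 arrays it was 0.47 for the labelled groups and 0.26 and 0.31 for the other 2 ways of pairing the 4 arrays. Those other pairings gave 28 and 346 features at an unadjusted p under 0.05, against 2817 for the labelled groups. By limma, 0 passed at an adjusted p of 0.05 in any of these. The smallest adjusted p was 0.0917 in the pairing with 346 features and 0.133 for the labelled groups. In the other pairings the difference between the labelled groups adds to the residual spread, which lowers their counts. The 28 and 346 therefore give no chance value for the 2817.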

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

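The naming of groups by the processed table, the crossed pairing and the count at an unadjusted p under 0.05 were added after seeing the data. With limma, 0 features passed in every alternative except 3: the replicate number as a block gave 6 (Mbp, Tubb4a, Fa2h, Rnd2, Ap2a1 and Enpp6, all lower, with Tubb4a, Fa2h and Enpp6 chosen after their values were seen), and leaving out each array in turn gave 0 to 5, with 1067 to 3533 at an unadjusted p under 0.05. The scanner headers carry no replicate number, so the block rests on the numbers of the matched columns of the processed table. Same-numbered arrays share only a number, and their deviations correlated at -0.19. The block by number left the same 5 lists past the threshold. The crossed pairing gave 0 features, 3248 at an unadjusted p under 0.05, and 4 lists, with DNA repair at an adjusted p of 0.0687. The 5 without control array 2 were Mbp, Mag, Xist, Eif2s3y and a probe without a gene name, chosen after their values were seen. Against 5 lists, 3 to 6 passed with an array left out, and 0 with an estimated correlation or fry. With 2 residual degrees of freedom the estimated correlation left all 41 lists at an adjusted p of 0.982 to 0.997. The astrocyte list with an estimate of 0.0426 was included, so that test separated no list from another. The estimates were 0.80 for the mitotic, 0.87 for the replication, 0.44 for the oligodendrocyte and 0.39 for the DNA repair list. The preset value of 0.01 is far lower, and at it camera takes the genes of a list as nearly independent. The mean replicate correlation moved from 0.984 to 0.966 without background correction, 0.991 without a filter and 0.9803 with the stricter detection filter. Bmi1 lay between -0.13 and 0.61 with an array left out and at -0.18 with the groups as the processed table names them, where 1273 features were higher and 1567 lower at an unadjusted p under 0.05. Cxcl12, whose other probe stood at -0.37, reversed to -0.34 with cyclic loess and -0.079 with median scaling, Ngfr to 0.019 with median scaling, and Cdkn2a to -0.54 and -0.07 without control array 1 and the first Bmi1 array, against 1.07 without control array 2. The cause was not tested. Of the other alternatives for single genes and lists, 1801 kept direction and side of the threshold, 7 gained a call and 23 lost one. Part of this was fixed beforehand. No single gene passed in the main fit, so only lists could lose a call. The block settings and the trend and robust setting leave every log2 difference as it was. The naming by the processed table, which turns the directions, is not in this count. Dim signal limits the genes with a detection p of 0.05 or more.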

Other observations

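Within the oligodendrocyte list, genes of later stages lay lower than those of the early lineage, in a split that did not pass its test. The 13 markers of differentiating and myelinating cells had a median log2 difference of -1.02 in the arrays labelled Bmi1 and 12 were lower, while the 6 markers of the early lineage had a median of -0.11 and 3 were lower. The mean difference between these sets was -0.98 (exact two-sided permutation p = 0.0526 over 27132 permutations of genes, which are not independent replicates). The early set went both ways, with Nkx2-2 at -1.16, Olig2 at -0.65, Sox10 at -0.31, Olig1 at 0.09, Pdgfra at 0.24 and Cspg4 at 0.46. In the later set Cnp stood at -1.36 and Enpp6 at -2.11. The log2 values of Enpp6 were 11.32 and 9.44 on control arrays 1 and 2, and 9.14 and 7.40 on the first and second Bmi1 arrays. Sox10, Olig1, Pdgfra, Cspg4, Cnp and Enpp6 were chosen after their values were seen. The 2 control arrays differed in the later set as well, at 1.13 and 0.00 relative to the mean of the 4 arrays. The first and second Bmi1 arrays stood at -0.09 and -1.21, so control array 2 and the first Bmi1 array lay close together.

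Of 159 gene families grouped by symbol stem, none passed with camera. The olfactory receptors, 36 features near background, had a median of 0.27 (adjusted p = 0.0519), and the kinesins, 23 features that include mitotic motors, a median of 0.47 (adjusted p = 0.230). These families and the split of the oligodendrocyte list were chosen after the data were seen.

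All tests in the paragraphs that follow were chosen only after the result was seen. The opposite naming of the groups in the 2 tables may come from a processed table whose columns were filled in alphabetical order of the array names, and 4 of 4 columns hold the array at that place. This stays open, because once both arrays headed 1DT are seen in the control columns only 4 orders remain, and 2 of these are alphabetical. A wrong set of scanner headers stays open too: the Bmi1 probe differed by 0.24 (SE 0.29) between the groups, too little to tell, and its place relative to the transgene is not known here. Cdkn2a, which Bmi1 represses, does not help, with a log2 difference of 0.27 (SE 0.50).

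Higher cell-cycle genes with lower oligodendrocyte genes could come from 1 unusual array or from variation between cultures. The genes of a list vary together, so the errors given here come from the spread of list medians between arrays of a group. With all arrays the mitotic median was 0.98 (SE 0.47) and the oligodendrocyte median -0.75 (SE 0.59). The dimmer second Bmi1 array cannot be told apart from the group as a cause, since the mitotic median without it was 0.80 (SE 0.57) and the oligodendrocyte median -0.47 (SE 0.72), nor can the sex of control array 1, the Xist-positive one, with 0.49 (SE 0.57) and -0.22 (SE 0.72) without it. Variation between cultures in how many cells divided or differentiated is compatible with the values of the mitotic and oligodendrocyte lists. Between the control arrays, the mitotic list differed by 0.834 of the group difference and the oligodendrocyte list by 1.43 times it. Between the arrays labelled Bmi1 the medians differed less, by 0.48 and -0.48, against group differences of 0.98 and -0.75. A difference between 2 single arrays also spreads more than one between means of 2 arrays, so these ratios overstate the part of culture variation. The astrocyte list varied less within groups than between them. Its median difference was -0.04 between the control arrays and -0.13 between the arrays labelled Bmi1, against -0.32 between groups. An effect of Bmi1 itself stays among the open explanations, and with 2 cultures per group it was not separated from these.

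Some probes of the same gene went opposite ways. Among 3763 genes with at least 2 detected probes, the log2 differences of the brightest pair correlated at 0.355 across genes, against 0.502 and 0.437 in the other pairings of the arrays, and of 303 with an unadjusted p under 0.05 for both probes, 243 had the same sign and 60 opposite signs. Noise of dim probes is an unlikely cause of all of these, since 19.1% (SE 3.31) of the 141 such pairs with both mean log2 values at 7 or more had opposite signs, against 20.4% of the 162 dimmer pairs. Examples, chosen after their values were seen, were Cdk4 at -0.78 and 1.63, and Lmna at 1.04 and -0.89. Shifts between transcript isoforms could not be tested, because probe positions were not used here.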
